A study of Mus musculus with 6 samples.

How the data were processed

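RNA of bone marrow-derived macrophages of 2 mouse genotypes was hybridised to 1-colour Agilent 4x44K whole mouse genome arrays of design 014868, with 1 array for each genotype and polarization state and 6 arrays in all. The groups were taken from the labels. Control cells (WT) carried the floxed Foxo1 gene without Cre, and knockout cells (KO) carried it together with a Cre recombinase driven from the lysozyme M gene, Lyz2. M0 stands for unstimulated cells, M1 for cells given lipopolysaccharide (LPS) and interferon-gamma, and M2 for cells given the interleukins IL-4 and IL-13.

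The authors deposited the scanner output of each array, whose spot intensity values (processed signal, mean signal and local background) come from Agilent Feature Extraction 10.7.3.1, per the file headers. Per the file headers, the processed signal is background-subtracted and detrended within the array and is not scaled between arrays. The authors also deposited a table of log2 values for the same arrays. Each of its columns correlated with the log2 processed signal of its own array with a Pearson r of at least 0.99886 across probes, and with no other array above 0.990. The 6 columns had medians between 5.39 and 5.41 and quantiles within 0.225 of their mean, and how they were centred is not given in the sources used here. That table served as an alternative.

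Control spots and spots with an outlier flag were left out (79 to 164 of 43379 spots per array), spots of a probe were averaged, and 37 of 41174 probes without a value on all arrays were dropped. The main scale was the log2 processed signal minus the array's 75th percentile. A gene, as named in the files, was represented by its probe with the highest mean over the 6 arrays. It was tested where that probe was well above background on at least 2 of 6 arrays, which left 19043 of 27376 gene names. Names were updated by accession or synonym through a RefSeq table of the GRCm38.p6 assembly, which is not that of the probe coordinates and was used for names only. By accession 27668 probes matched, 5589 carried a current symbol, 471 matched a synonym, and 7446 stayed without a symbol. Probe coordinates are those of the files, on mm9 (NCBI37).

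With limma 3.58.1 in R 4.3.3, an additive model with terms for state and genotype was fitted to all 6 arrays, with empirical Bayes moderation (prior df 1.88, 2 residual df) and Benjamini-Hochberg adjustment. Because each genotype and state has 1 array, the residual of this model mixes array noise with genotype differences that vary between states, and its p-values measure only that spread. Nothing in the labels says whether the 6 RNA samples came from separate animals. Differences between genotypes within a state, and differences of these between states, are values of 1 array against 1 array, with no replicate check and no p. Where a group was not well above background on any of its arrays, a bound is given as "at least N-fold": the bright side's mean against, on each dim array, the higher of the lowest well-above-background signal and the probe's own value.

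The 34 gene lists were fixed before the data were examined. Those with at least 5 tested genes (31) were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera passed 0 lists in any comparison. Even the M1 polarization list in M1 against M0, where 23 of 25 genes passed, then had an adjusted p = 0.634. A failure with an estimated correlation therefore decides nothing about a list. The estimated correlations ran from -0.0375 (LXR and PPAR lipid genes) to 0.926 (interferon-gamma GTPases). They were 0.335 for MHC class II, 0.732 for granulocyte, 0.581 for stromal and 0.657 for cell cycle genes. Where members are correlated beyond the preset of 0.01, the adjusted p at the preset is too small and does not measure the strength of evidence. Within a state a list is described by the percentile of its median among 10000 random lists matched on mean signal in 20 bins. For the MHC class II list an exact sign-flip permutation test over the 3 states was also run. The named genes were likewise fixed by a rule: Foxo1, Foxo3, Foxo4, Lyz2 and the tested MHC class II genes; then, because fewer than 10 genes passed for KO against WT, up to 10 genes higher and 10 lower by at least 2-fold in all 3 states, ranked by their smallest difference. These were limited here, beyond the rule, to genes well above background on all 6 arrays, which left out Fmr1nb, Efcab6 and Aloxe3 among the higher and Ngp, Kcnj10 and Sparcl1 among the lower genes. Within a state the rule took the 5 highest and 5 lowest genes well above background on both arrays. For M1 and M2 it took the 12 highest and 12 lowest genes past an adjusted p of 0.05 and at least 2-fold by mean difference, with the same direction in both genotypes, limited here to genes well above background on all 4 arrays, since values at the floor have no order, and the members of the M1 and M2 lists. Between states it took the 5 highest and lowest differences among genes well above background on all 4 arrays compared, and for a gene list 2 to 4 members with the largest difference; in the text, a member's difference within a state is left out where an array of that state was not well above background, members already named elsewhere are mostly not repeated, and Cat, Clec7a, Fbxo32 and Pik3ip1, which went against other members of their lists, and the p53 targets and Alb were chosen after their values were seen. Only genes with a symbol were named. Some genes that the rule takes are not reported here.

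Alternatives were quantile normalization, median centring, normexp background correction on mean and background signal (offset 50) with quantile normalization, the deposited table, other filters on dim probes, the mean of all probes of a gene, the slide as a block, each array left out in turn, a trend or robust variance prior, and other thresholds. Slide and scan were read from the array files as slide 1 (WT M0, WT M1) and slide 2 (WT M2 and the 3 KO arrays), each scanned together. For KO against WT the slide block leaves the M2 pair alone, 1 array against 1 array. An adjusted p from that setting carries no replicate check, whether a list passes or fails. Leaving out 1 array takes the whole pair of its state out of the KO against WT difference.

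The fit was tested on simulated data for 19043 genes with the prior variances of the real fit and 50 changed genes at each of 4 fold sizes. For KO against WT it called 0% of the changed genes at 2-fold, 40% at 4-fold, 88% at 8-fold and 80% at 16-fold, with 5 false calls. For M1 against M0 it called 0% at 4-fold, 38% at 8-fold and 68% at 16-fold, with 1 false call. For M2 against M0 it called 2% at 4-fold, 42% at 8-fold and 64% at 16-fold, with 2 false calls. The real M1 comparison passed 4873 genes, many more than were changed in the simulation. The Benjamini-Hochberg cutoff is stricter where fewer genes change, so the simulated M1 shares do not apply to the real M1 comparison. For the same reason the simulated KO shares need not hold for the real KO comparison. There Rhox5 (mean 3.77), Slc23a3 (3.23) and Foxo1 (-2.78) each had an adjusted p of 0.305 in limma. A real count of 0 for KO therefore does not show that large differences are absent. Between 63.1% and 67.9% of spots per array were well above background and none was saturated. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.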

Results

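The series concerns the transcription factor FoxO1 in macrophages, MHC class II expression and the anti-tumour effect of tumour-associated macrophages. Bone marrow cells were grown for 7 days in medium with 10% L929-conditioned medium, a source of macrophage growth factor, and then polarized for 24 hours. M1 cells received 100 ng/ml LPS with 20 ng/ml interferon-gamma, and M2 cells received 10 ng/ml IL-4 with 10 ng/ml IL-13. M0 cells received neither. Each of the 6 combinations of genotype (WT or KO for Foxo1) and state had 1 array, so no value below has a replicate of its own. The 75th percentile of the processed signal lay between 532 units (WT M0) and 627 units (KO M2). Levels are log2 signals relative to that percentile, and differences are on the same log2 scale.

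Some arrays carried transcripts typical of liver. Albumin (Alb) read 3.48 on WT M0, -2.37 on KO M1 and between -8.37 and -5.96 on the other arrays. The alpha-1 antitrypsin gene Serpina1d read 3.55 on WT M0, -0.75 on KO M1 and at most -4.38 elsewhere. Over 38 tested liver transcripts, a list made after such genes were seen, the median was -1.04 on WT M0, -4.40 on KO M1 and between -6.87 and -5.62 on the other arrays. Genes at least 2-fold brighter than on every other array numbered 293 on WT M0, 202 on WT M2, 195 on KO M1, 52 on KO M2, 27 on WT M1 and 12 on KO M0. Comparisons that use the WT M0 or KO M1 array carry these transcripts.

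**Figure D1:**
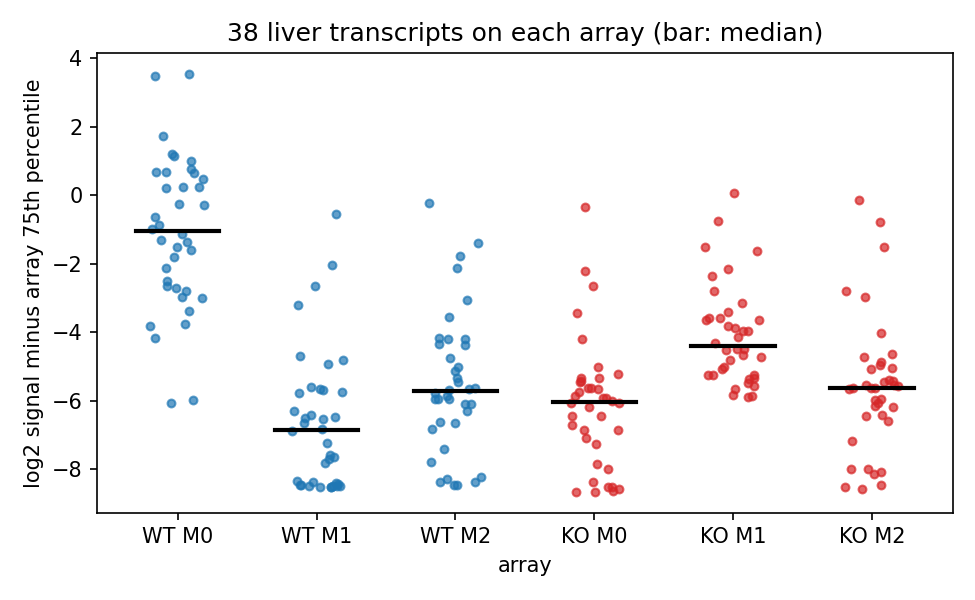
Log2 signal relative to the array's 75th percentile (y axis) of 38 liver transcripts on each of the 6 arrays (x axis), with 1 point per gene, the median as a bar and sideways scatter for legibility. The median was -1.04 on WT M0 and -4.40 on KO M1, and at most -5.62 on the others.

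The first question was whether Foxo1 itself differed between the genotypes. Foxo1 was lower in KO in every state: KO minus WT was -2.92 in M0, -2.78 in M1 and -2.65 in M2. Its processed signal was 1505, 1144 and 1559 units on the WT arrays and 224, 165 and 282 units on the KO arrays, in the order M0, M1, M2. The mean difference was -2.78 ± 0.13 (SE), with an adjusted p of 0.305 in limma. Its probe lies on chromosome 3 from 52150183 to 52150242 (mm9) and reads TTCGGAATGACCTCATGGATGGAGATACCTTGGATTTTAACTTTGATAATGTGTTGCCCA. A further Foxo1 probe from 52153289 to 52153348 gave -2.80, -2.90 and -2.90. The labels do not say which part of the gene is deleted, and the files do not place the probes in exons. Of the related factors, Foxo3 differed by -0.22, 0.25 and 0.21 and Foxo4 by 0.87, 0.20 and 0.01 in M0, M1 and M2, and Foxo6 was not well above background on any array. For Lyz2, the gene that drives Cre, the brighter probe differed by 0.48, 0.74 and -0.78 and the other by -0.81, -0.92 and -0.01, so its probes disagree.

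The comparison of KO with WT over all states asks which macrophage genes differ between the genotypes regardless of polarization. Only the KO cells carried Cre, so effects of Foxo1 loss and of Cre cannot be told apart. Rhox5, a homeobox gene, was higher in KO by 4.10 in M0, 3.22 in M1 and 3.98 in M2 (mean 3.77 ± 0.23, SE). Cd5l, a secreted scavenger-receptor protein of macrophages, was higher by 2.17, 2.48 and 3.06 (mean 2.57 ± 0.22, SE), and Slc23a3 by 2.86, 3.31 and 3.51. Phlda3, Gtse1 and Ddias (4632434I11Rik in the files), known as p53-responsive genes, were higher by at least 1.71, 1.64 and 1.59 in any state. The histone genes Hist1h4i and Hist1h2bq were higher by at least 2.30 and 1.92, and Fnd3c2 and Noxred1 by at least 1.92 and 1.91. Hist1h2ac was well above background in KO only, at least 5.25-fold over WT (adjusted p of 0.384 in limma).

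Genes at least 2-fold lower in KO in every state included, beside Foxo1, S100a9, a calcium-binding protein abundant in neutrophils (-2.64, -2.14 and -2.60; mean -2.46 ± 0.17, SE), and the collagen gene Col1a1 (-2.35, -2.00 and -1.81). The membrane protein genes Tmem176b and Tmem176a differed by -2.47, -1.70 and -2.55 and by -2.61, -1.66 and -2.51. Cd79b, a B cell receptor subunit, differed by -2.03, -1.86 and -1.63. Ly6a differed by -4.31 in M0, -1.64 in M1 and -1.61 in M2, with a mean of -2.52. Ly6c2, a marker of inflammatory monocytes, differed by -3.43 in M0, -1.39 in M1 and -1.50 in M2. The collagen gene Col3a1 differed by -1.78, -1.87 and -1.39.

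None of these genes passed. In limma 0 of 19043 genes passed an adjusted p of 0.05 for KO against WT (lowest 0.305), while 2157 had an unadjusted p under 0.05 (1299 higher and 858 lower), where 952 would be expected by chance; a variance prior with an intensity trend called 32. Among 15877 genes well above background on all arrays, 39 were at least 2-fold higher and 32 at least 2-fold lower in KO in all 3 states, where 1.80 and 0.146 would be expected if the states were independent. In M0 and M1 the genotypes lay on different slides, and only the M2 pair shared a slide. KO minus WT in M0 correlated with that in M1 (Pearson r = 0.523), so the states were not independent. The excess over the expected numbers therefore does not by itself measure a genotype effect.

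MHC class II genes, which present peptides to CD4 T cells, had lower values in KO in M0 and M2 and smaller differences in M1. Ciita, the transactivator of the class II genes, differed by -2.38 in M0, -0.13 in M1 and -1.33 in M2. H2-Aa differed by -1.43, -0.49 and -1.15, H2-Ab1 by -1.27, -0.30 and -0.63, and H2-Eb1 by -1.25, -0.08 and -0.94. The invariant chain gene Cd74 differed by -1.06, -0.42 and -0.91, and the peptide-loading genes H2-DMa and H2-DMb1 by -1.17, -0.09 and -0.91 and by -0.63, 0.21 and -0.86. The dimmer H2-DMb2 and H2-Oa gave -0.13, -1.13 and -0.87 and 0.40, -0.16 and -0.65. H2-Ea, H2-Eb2 and H2-Ob were not well above background on enough arrays to be tested.

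The median of the 9 tested class II genes was -1.17 in M0, -0.16 in M1 and -0.91 in M2, at the 0.00, 1.73 and 0.00 percentiles of 10000 matched random lists. Its mean over the states was -0.75 ± 0.52 (SD, n = 3 states), with an exact two-sided sign-flip permutation p of 0.25, the smallest that 3 pairs can give. Camera of limma put the list lower in KO at an adjusted p of 5.13e-06; the adjusted p = 0.767 with an estimated correlation and 0.346 with fry, and 0 of 9 genes passed, also adjusted over the list alone. With the slide as a block the list's median was -0.91, which rests on the M2 pair. Without either M0 array the mean was -0.54, which is that of the M1 and M2 pairs, since the M0 pair then drops out. The 11 factors that act on class II promoters, such as Nfyb (0.35, 0.29 and 0.40) and Rfxank (-0.02, -0.37 and -0.34), had medians of -0.02, 0.13 and -0.34 and an adjusted camera p of 0.550 in limma.

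**Figure D2:**
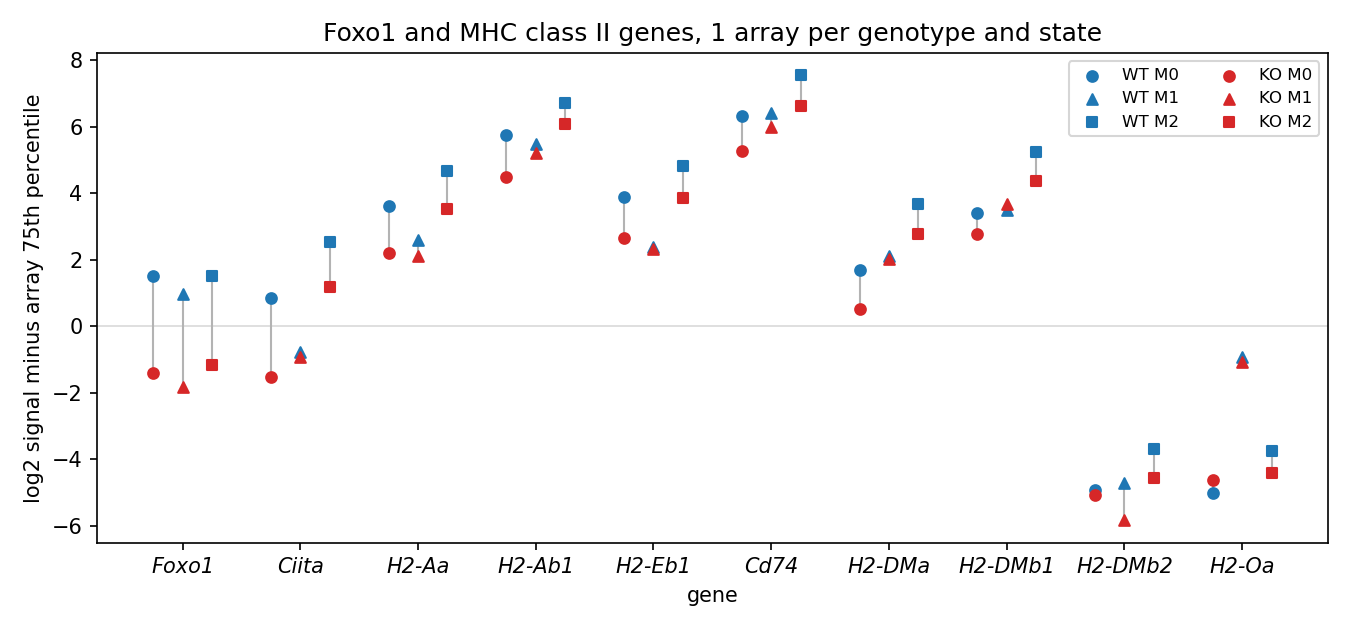
Log2 signal relative to the array's 75th percentile (y axis) of Foxo1 and the 9 tested MHC class II genes (x axis), with 1 point per array, colour for genotype, shape for state and a grey line joining WT and KO of a state. KO minus WT of Ciita was -2.38 in M0 and -0.13 in M1.

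Markers of other cells also differed between the genotypes. Neutrophil and granulocyte markers had KO minus WT medians of -2.16 in M0, 0.16 in M1 and -1.37 in M2, with Ngp at -3.07 in M0 and -2.48 in M2 and the lactoferrin gene Ltf at -3.01, -1.32 and -2.49. Both arrays were well above background for 11, 7 and 9 of the 15, and with the others at their bounds the medians were -2.16, 0.18 and -0.81. The list's median in the additive model was -0.99, against -0.37 with normexp correction and -0.50 for genes well above background on all 6 arrays. With arrays left out it ran from -1.67 (without either M1 array) to -0.62 (without either M0 array). Stromal and fibroblast markers had medians of -1.41, -0.63 and -0.76, and 14 of 16 were lower in every state, among them Thy1 (-2.32 in M0 and -0.53 in M1) and Col6a1 (-1.94, -0.93 and -1.34). Their median in the additive model was -1.01, against -0.58 with normexp correction and -0.57 with the mean of all probes of a gene. Monocyte and progenitor markers had medians of -0.59, -0.11 and -0.64. Among them the chemokine receptor gene Ccr2 differed by -2.13, -0.91 and -2.26 and F13a1 by -1.99 in M0 and -2.29 in M2. With dim genes at their bounds the M0 median was -0.44. In M1 both arrays were well above background for 8 of the 13, and the median of those was -0.84. Camera of limma put these 3 lists lower in KO at adjusted p of 7.24e-08, 2.68e-13 and 0.00452; the adjusted p = 0.767 for each with an estimated correlation. Adjusted over the list alone, 3 of 15 neutrophil, 12 of 16 stromal and 5 of 13 monocyte markers were lower and 1 monocyte marker, Gata2 (1.02 in M0), was higher, against 0 over all genes. The monocyte list lost its call with the slide as a block (adjusted p = 0.0944) and without WT M2 or KO M2 (adjusted p = 0.0658). B cell (medians 0.47, 0.71 and -0.20), T and NK cell (-0.18, 1.07 and -0.05), mast cell (0.54, 1.08 and -0.09), erythroid (0.20, 0.43 and -0.22), dendritic cell (-0.10, 0.72 and -0.40) and osteoclast markers (0.21, 0.66 and -0.31) did not pass camera. With dim genes at their bounds the B cell medians were 0.10, 0.38 and -0.20, the T and NK cell median in M1 was 0.66, and the mast cell medians were 0.18, 0.43 and -0.21. Adjusted over the list alone, 1 B cell marker (Cd79b) and 1 mast cell marker (Il6ra) were lower and 1 osteoclast marker (Ctsk) was higher.

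Cell cycle genes had medians of -0.46, 0.07 and -1.15 and an adjusted camera p of 5.07e-08 in limma (adjusted p = 0.767 with an estimated correlation). The thymidine kinase gene Tk1 differed by -1.13, -0.80 and -2.04 and the ribonucleotide reductase gene Rrm2 by -1.52, -0.20 and -1.87. NRF2 oxidative stress genes had medians of 0.31, 0.34 and 0.31 and an adjusted camera p of 0.000920 in limma (adjusted p = 0.767 with an estimated correlation), with the cystine transporter gene Slc7a11 at 1.30, 0.70 and 0.85. Tumour-associated macrophage genes had medians of -0.69, -0.04 and -0.40, with Il10 at -1.55, -0.51 and -1.13. Their adjusted camera p was 0.000544 in limma (adjusted p = 0.767 with an estimated correlation), and 1 of 23 was lower adjusted over the list alone. With the slide as a block their adjusted p was 0.275. Interferon-gamma GTPases (medians -1.01, 0.50 and -0.52) and type I interferon response genes (-0.78, 0.32 and -0.05) had medians of opposite sign in M0 and M1, and adjusted camera p of 0.0130 and 0.0227 in limma (adjusted p = 0.847 and adjusted p = 0.898 with an estimated correlation). Without WT M0 or KO M0 these were 0.694 and 0.163, and the second list then pointed upward, as it also did with the slide as a block. M2 polarization genes had medians of -0.37, 0.35 and -0.45, cholesterol synthesis genes 0.15, -0.34 and -0.35, and immediate early and heat shock genes 0.08, 0.50 and 0.07. Their adjusted camera p was 0.0499, 0.00222 and 0.0461 in limma (adjusted p = 0.847, 0.847 and 0.767 with an estimated correlation). The M2 polarization list missed the threshold with every other scaling, from 0.0528 with median centring to 0.0739 with normexp correction, and with the slide as a block (0.0608). The immediate early and heat shock list missed it with the slide as a block and with the authors' table, and both it and the cholesterol list did so without any 1 of the M1 or M2 arrays.

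In all, 12 of 31 lists passed camera of limma for KO against WT (10 lower and 2 higher). With an estimated correlation 0 did, at a lowest adjusted p = 0.767, and with fry 0 did. The test with an estimated correlation also passed 0 lists for M1 and for M2, so it cannot part changed from unchanged lists here. With the slide as a block the KO against WT difference is that of the M2 pair alone, with no replicate check. List medians were then -0.91 for MHC class II, -1.37 for granulocyte and -0.76 for stromal genes. They were -1.15 for cell cycle, -0.35 for cholesterol and 0.31 for NRF2 genes. Without WT M2 or KO M2 6 passed, and the NRF2 list did not (adjusted p = 0.0963). FoxO target genes had medians of 0.06, 0.29 and 0.04 and an adjusted camera p of 0.799 in limma, with the cell cycle inhibitor gene Cdkn1a at 1.65, 0.88 and 1.66, Gadd45a at 0.49, 1.25 and 1.71 and Pik3ip1 at -1.16, 0.08 and -1.52.

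**Figure D3:**
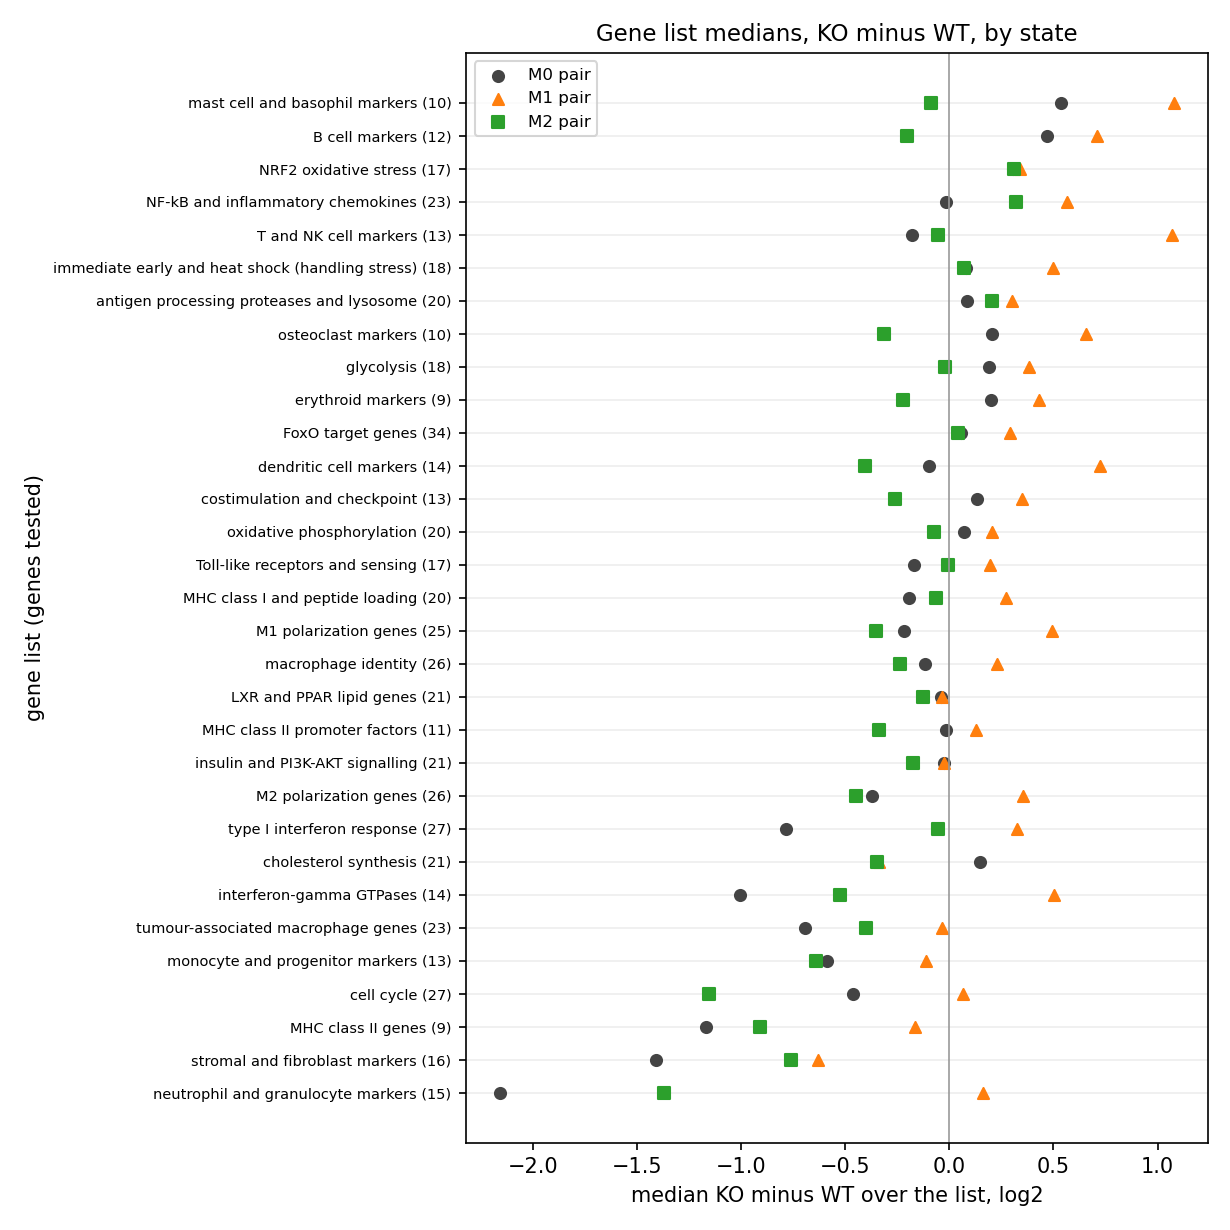
Median KO minus WT in log2 (x axis) of each gene list with at least 5 tested genes (y axis, number of tested genes in brackets), with 1 point per state. Neutrophil and granulocyte markers had the lowest median, -2.16 in M0.

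Within single states, 1982 genes in M0 (1259 higher and 723 lower in KO), 2156 in M1 (1952 higher and 204 lower) and 1283 in M2 (496 higher and 787 lower) were at least 2-fold apart. At 4-fold the balance in M0 turned, with 68 higher and 146 lower. The lowest genes in KO in M0 were the liver transcripts Serpina1d (-8.87), Fgb (-6.70), Mup3 (-6.35), Mup4 (-5.50) and Cyp3a41a (-5.34). The highest in M0 were Rhox5, the alternative activation gene Retnla (3.28), Slc23a3, the glutamate receptor gene Grin2d (2.77) and the lactate transporter gene Slc16a8 (2.75). Grin2d and Slc16a8 were low on both slide 1 arrays, WT M0 (0.96 and -3.41) and WT M1 (0.72 and -3.22). In M1 the highest were Serpina1d (4.91), the immediate early genes Egr1 (4.16) and Arc (3.78), the growth factor gene Hbegf (3.67) and Myl3 (3.64). The lowest in M1 were Foxo1, S100a9, Cwh43 (-2.06), Slc16a9 (-2.05) and Abhd15 (-2.02). In M2 the highest were Rhox5, Ddit4l (3.71), Slc23a3, the kinase gene Dyrk3 (3.48) and Cd5l, and the lowest were the forkhead gene Foxq1 (-2.67), Foxo1, S100a9, Tmem176b and the aquaporin gene Aqp3 (-2.51).

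The split into higher and lower depended on the scaling. In M1 90.5% of the genes at least 2-fold apart were higher in KO, against 65.9% after quantile normalization and 79.5% after normexp correction. In M0 the share was 63.5%, against 36.6% after normexp correction. Apart from scaling, the 293 genes at least 2-fold brighter on WT M0 than on every other array are lower in KO in M0 by their definition, and 430 of the 723 lower genes in M0 are not among them, a count chosen after the liver transcripts were seen. The median KO minus WT of all tested genes in M1 was 0.13 on the main scale and -0.19 after median centring.

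The difference between the states asks whether KO and WT differ more in some states than in others. Across genes, which are not independent replicates, KO minus WT in M0 correlated with that in M1 (Pearson r = 0.523, Spearman rho = 0.533, 15877 genes). The values were 0.141 and 0.142 between M0 and M2, and -0.0225 and -0.0115 between M1 and M2. The M0 and M1 pairs lie across slides and the M2 pair within 1 slide. Among genes well above background on all 4 arrays compared, KO minus WT moved up most from M0 to M1 for the liver transcripts Serpina1d (13.78), Mup3 (7.63), Gc (6.79) and Cyp3a41a (6.47) and for the immunoglobulin gene Iglv1 (5.82). It moved down most for Olfr1221 (-2.91), Olfr522 (-2.76), Fat2 (-2.63), the secretin gene Sct (-2.39) and Cldn26 (-2.20). From M0 to M2 it moved up most for Serpina1d (8.53), Iglv1 (5.61), Mup3 (5.50), Apoa2 (5.34) and Gc (5.11), and down for Foxq1 (-4.88), Slc16a8 (-4.87), Trim54 (-4.36), Grin2d (-4.29) and Mxd3 (-4.28).

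The comparison of M1 with M0 addresses the response to LPS and interferon-gamma. Of 25 M1 polarization genes, 23 rose and 0 fell in limma (23 adjusted over the list alone), with a median of 5.03. The inducible nitric oxide synthase gene Nos2 rose at least 694-fold, Cxcl11 at least 2235-fold, Il6 at least 204-fold and Il12b at least 86.8-fold. The interferon-induced chemokine gene Cxcl9 rose by 11.23 ± 0.67 (SE), the prostaglandin synthase gene Ptgs2 by 8.59 ± 0.52 and Irg1, which makes itaconate, by 8.08 ± 0.18, at adjusted p of 0.00709, 0.00709 and 0.00584 in limma. Tnf rose by 4.09 and Il1b by 4.82, while Socs3 (0.50) and Il27 (0.79) did not pass.

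Other genes that rose most were Gbp4 (10.60), the cystatin gene Cst7 (8.93), Slfn4 (8.24), Serpina3g (7.87), Dnase1l3 (7.68), Ccl12 (7.34), Cd69 (7.11) and Gbp6 (7.11). The genes that fell most were Ptgs1 (-6.99), the sorting receptor gene Sort1 (-6.50), the sphingomyelinase gene Smpd3 (-6.27), Samd4 (-6.17), the lipase inhibitor gene Angptl4 (-5.94), Nat8l (-5.92), Cmbl (-5.81), Kctd12b (-5.73), Zfyve28 (-5.69), Cfhr2 (-5.54) and Matk (-5.53). Their adjusted p in limma lay between 0.00584 and 0.0122.

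All 27 type I interferon response genes rose (median 3.67), led by Ifi205 (6.60), Oasl1 (6.12) and Isg15 (5.44), as did all 14 interferon-gamma GTPases (median 4.48). Of 20 MHC class I and peptide loading genes 14 rose (16 adjusted over the list alone), such as Tap2 (3.16) and Nlrc5 (3.16), whereas of 9 MHC class II genes 1 rose, H2-Oa (3.83). Of 18 glycolysis genes 14 rose (17 adjusted over the list alone), with the lactate exporter gene Slc16a3 at 3.41 and Pfkfb3 at 3.18. NF-kB and chemokine genes rose in 15 of 23 cases (16 rose and 1 fell adjusted over the list alone), with Ccl7 at 6.58 and Ccl2 at 6.12. Immediate early and heat shock genes rose in 7 of 18 (10 adjusted over the list alone), with Hspa1a at 4.30. NRF2 genes rose in 8 of 17, with the superoxide dismutase gene Sod2 at 3.18, and the catalase gene Cat fell (-0.90); adjusted over the list alone 8 rose and 3 fell.

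Of 21 LXR and PPAR lipid genes 9 fell and 3 rose (11 and 3 adjusted over the list alone), with Pparg at -2.91 and Fabp4 at -2.31. Granulocyte markers fell in 5 of 15 cases (8 fell and 1 rose adjusted over the list alone), with Ngp at -5.58. Ngp was not well above background on KO M1, so this value rests in part on a reading near the floor. Stromal markers fell in 11 of 16 (12 fell and 2 rose adjusted over the list alone), with Pdgfra at -3.44. Cell cycle genes fell in 9 of 27 cases (12 adjusted over the list alone), with Ccna2 at -3.98, while the cyclin gene Ccne1 rose (4.14). Of 26 M2 polarization genes 11 fell and 7 rose (13 and 7 adjusted over the list alone), with the mannose receptor gene Mrc1 at -5.49 and the arginine transporter gene Slc7a2 at 6.27. Camera of limma passed 12 of 31 lists for M1 (8 up and 4 down). With an estimated correlation 0 did, at a lowest adjusted p = 0.634, and with fry 11 did. These were not all the same lists. The granulocyte, stromal and cell cycle lists missed with fry (adjusted p = 0.0737, 0.0544 and 0.168). The costimulation list and the insulin and PI3K-AKT list passed fry (adjusted p = 0.0226 and 0.0132) but not camera.

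In all, 4873 of 19043 genes passed in limma for M1 against M0, 2202 higher and 2671 lower, of which 1665 and 2209 were at least 2-fold apart. Of genes changed M1 against M0, after median centring 58.8% of 4591 were higher, against 45.2% on the main scale, and the median of all genes moved from 0.03 to 0.26. The response correlated between WT and KO across genes (Pearson r = 0.887), and the M1 and M0 arrays of each genotype shared a slide. Without any 1 of the WT M0, WT M1, KO M0 or KO M1 arrays 0 genes passed.

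The comparison of M2 with M0 addresses alternative activation by IL-4 and IL-13. The checkpoint ligand gene Pdcd1lg2 rose by 7.01 ± 0.21 (SE), Slc7a2 by 5.56 ± 0.25 and Cdh1, the E-cadherin gene, at least 11.9-fold, each at an adjusted p of 0.0448 in limma. Hebp2 (4.95), the nucleotide synthesis gene Prps1 (3.63) and the transcription factor gene Nfil3 (3.08) rose, and Emr4 (-5.09), Pilrb1 (-4.26) and Pilra (-3.71) fell. Of 26 M2 polarization genes (median 4.80) 3 rose over all genes, and 23 rose and 1 fell adjusted over the list alone. Retnla (11.51), Arg1 (10.86), Chi3l4 (8.66), Flt1 (6.94), Ccl17 (6.81) and Mgl2 (6.20) had adjusted p between 0.0521 and 0.0629 over all genes in limma. Mrc1 stood at 1.28 and Clec10a at 0.85.

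In the lists that follow no member passed over all genes. MHC class II genes had a median of 1.30 in M2 against M0, and 7 of 9 rose adjusted over the list alone, with Ciita at 2.19 and H2-DMa at 2.13. Cholesterol synthesis genes had a median of 0.93 (15 of 21 rose adjusted over the list alone), with Idi1 at 1.68, and oxidative phosphorylation genes one of 0.56, with Ppargc1b at 3.19. Type I interferon response genes had a median of -1.88 (20 of 27 fell adjusted over the list alone), with Ifit3 at -4.38, and NF-kB and chemokine genes one of -0.89 (14 of 23 fell and 1 rose), with Nfkbiz at -3.33. Camera also put lower interferon-gamma GTPases (median -0.99), stromal markers (-0.91), granulocyte markers (-1.17), M1 genes (-0.34, with Cxcl10 at -4.99), tumour-associated macrophage genes (-0.31), Toll-like receptor genes (-0.28, with Cd14 at -3.02), FoxO targets (-0.15) and macrophage identity genes (-0.11). Camera of limma passed 14 of 31 lists for M2 (4 up and 10 down); with an estimated correlation 0 did, at a lowest adjusted p = 0.735, and with fry 0 did.

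For M2 against M0 16 genes passed in limma (12 higher and 4 lower), while 3645 had an unadjusted p under 0.05, where 952 would be expected by chance. The number of genes changed M2 against M0 was 147 with quantile normalization (61.9% higher), 478 with median centring (47.5% higher) and 860 with normexp correction (44.7% higher). With the slide as a block, or without any 1 array, 0 passed. The response correlated between the genotypes with a Pearson r of 0.631 across genes; WT M0 and WT M2 lie on different slides and KO M0 and KO M2 on 1 slide.

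**Figure D4:**
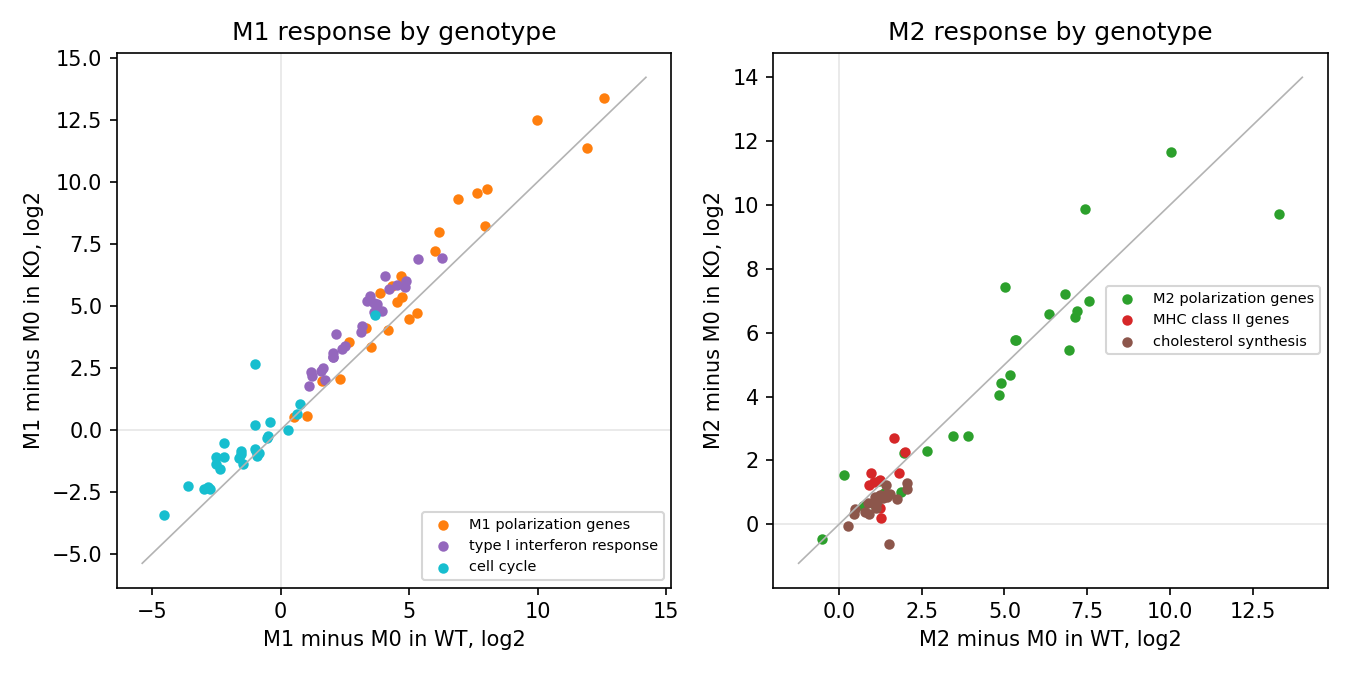
Difference from M0 in log2 in WT (x axis) and KO (y axis) for members of 3 gene lists in M1 (left) and M2 (right), with 1 point per gene and a grey line of equal response. M1 polarization genes had a median of 5.03 in M1, and M2 polarization genes 4.80 in M2.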

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

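The tests of liver transcripts were set up after such transcripts had been seen on the WT M0 and KO M1 arrays, on liver genes whose values had not been looked at.

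For 15 named genes KO minus WT had opposite signs, each at least 2-fold, in different states with both arrays well above background; these differences were not tested, since each value compares 1 array with 1 array. Serpina1d was 13.78 higher in M1 (4.91) than in M0 (-8.87), Mup3 7.63 higher (1.28 against -6.35), Gc 6.79 higher (1.63 against -5.16), Cyp3a41a 6.47 higher (1.14 against -5.34), Iglv1 5.82 higher (1.46 against -4.36) and Gbp6 2.20 higher (1.04 against -1.16). Fat2 was 2.63 higher in M0 (1.29) than in M1 (-1.34), and Sct 2.39 higher (1.21 against -1.18). Foxq1 was 4.88 higher in M0 (2.20) than in M2 (-2.67), Slc16a8 4.87 higher (2.75 against -2.12), Mxd3 4.28 higher (1.87 against -2.41) and Olfr522 3.84 higher (2.72 against -1.12). Trim54 was 4.57 higher in M1 (2.49) than in M2 (-2.08), Grin2d 4.33 higher (2.81 against -1.52) and Serpina3g 3.09 higher (1.60 against -1.49).

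Fgb (-6.70 in M0, at least 2.13 in M1), Mup4 (-5.50, at least 2.68) and Apoa2 (-5.03, at least 1.54) also had opposite signs but are not among the 15, since WT M1 was not well above background. Of the 15, Serpina1d, Mup3, Gc and Cyp3a41a had the largest differences, and these genes are typical of liver, as is Alb (3.48 on WT M0, -2.37 on KO M1), also not among the 15. Liver RNA in those samples is a candidate explanation. Of 30 liver genes not looked at before, 15 were tested; on WT M0 their median lay 2.99 above the mean of the other arrays, at the 100 percentile of matched random lists, and on KO M1 0.76 above (WT M0 left out), at the 99.6 percentile, with 15 of 15 higher. Between 5 and 12 of the 15 were also well above background on the remaining arrays, and whether macrophages themselves express these was not tested. How liver RNA came into the samples was not tested, and no biological explanation was tested.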

How the results depend on the processing

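One alternative, the M0 count without genes brighter on WT M0 (1689), was chosen after seeing the data and can only remove genes lower in KO; all others were planned. The cause of the shifts below was not tested, except that a left-out array leaves fewer residual df. The slide as a random block could not be fitted, since no gene gave a correlation estimate. For KO against WT 0 genes passed under every alternative except the trend prior (32), and the M2 pair on 1 slide, a count with no test, had 1283 genes at least 2-fold apart. The number of genes changed M1 against M0 ran from 0 to 5444 with arrays left out and from 3684 to 7178 otherwise. The number of genes changed M2 against M0 was 147 (quantile), 478 (median centring), 860 (normexp), 153 (the authors' table), 275 (above background on all arrays), 451 (adjusted p under 0.10), 1083 (trend prior) and 0 with no filter, with the slide as a block, with a robust prior and with any array left out (0 to 0).

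KO gene lists that passed numbered 0 with an estimated correlation, 0 with fry and 6 to 12 with arrays left out. The slide block is left out of this count, since it leaves the M2 pair alone, 1 array against 1 array. M1 lists numbered 0 and M2 lists 0 with an estimated correlation, and M2 lists 0 with fry. The class II median ran from -1.04 to -0.54 with arrays left out and was -0.61 with no filter. Foxo1 stayed between -2.88 and -2.42, at adjusted p of 0.0744 to 0.964 in limma. Within states, the 2-fold counts were 377 in M0, 219 in M1 and 384 in M2 with normexp and 1362 in M1 with quantile normalization; 4-fold counts were 214, 141 and 114.

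The value of Foxo3 KO against WT changed sign with median centring (-0.011), with normexp (-0.012) and without either M1 array, and ran from -0.0056 to 0.23 with arrays left out. That of Lyz2 KO against WT changed sign with the mean of its probes (-0.22), with the slide as a block (-0.78) and without an M0 or M1 array (-0.15 to 0.61 over all arrays left out). That of H2-Oa KO against WT ran from -0.41 to 0.12, above 0 without either M2 array. Of 1129 values of named genes under alternatives 908 kept their direction and a further condition. For tested values this was the side of the threshold, and for values within or between states, which have no test, a fixed fold margin. Another 162 no longer passed, 47 untested values moved beyond the margin and 12 changed sign. Since none passed for KO against WT on the main scale, those values could not lose a call. Dim spots limit these arrays, as 63.1% to 67.9% were well above background.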

Other observations

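The tests of slides and of dendritic cells for the MHC class II genes, and of splits at an adjusted p, were chosen only after the result was seen; the p53 hypothesis came from genes already seen and was tested on others.

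In 3 further lists members changed in both directions in M1 against M0. Of 13 costimulation and checkpoint genes 7 rose and 2 fell in limma (7 and 2 adjusted over the list alone), with Cd40 at 5.07, Cd86 at 4.93 and the checkpoint ligand gene Cd274 at 4.05. Of 17 Toll-like receptor and sensing genes 6 rose and 1 fell (8 and 2 adjusted over the list alone), with Nod2 at 2.67 and the beta-glucan receptor gene Clec7a at -1.53. Of 34 FoxO target genes 9 rose and 10 fell (10 and 11 adjusted over the list alone), with Ccnd2 at 3.79, Trib3 at 3.37, Sesn1 at -3.82 and Fbxo32 at -3.07. Camera of limma passed none of these 3 lists in M1, at adjusted p of 0.0880, 0.156 and 0.722. With fry the adjusted p was 0.0226, 0.0544 and 0.0744, so the costimulation list passed there.

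p53 target genes had higher values in KO in every state. Higher p53 activity in the KO arrays may account for this: 24 targets not looked at before had medians of 0.64 in M0, 0.56 in M1 and 1.26 in M2, with 22, 22 and 21 of 24 higher, at the 100 percentile of matched random lists in each state. Among them Mdm2 differed by 1.38, 0.66 and 2.11, Ccng1 by 1.30, 0.89 and 1.52 and Sesn2 by 1.28, 0.99 and 2.16. A difference between slides as the whole cause is argued against by the M2 pair, which shares a slide and lay at the 100 percentile. Foxo1 loss, the Cre carried only by KO cells and the single culture behind each KO array stay open. There was no replicate and no WT culture with Cre.

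MHC class II genes had lower values in KO in M0 and M2. In M2 both arrays share a slide and the list's median was still -0.91, while the liver genes stood at 0.063, so neither slide nor liver RNA is likely to explain the M2 difference. In M0 the liver genes stood at -1.98, so a foreign tissue in the WT sample and the genotype cannot be told apart there, nor in M2 can the genotype and the single WT sample, whose array had 202 genes at least 2-fold brighter than on every other. Fewer dendritic cells in KO stay open: their markers had medians of -0.10 in M0 (bootstrap interval -0.54 to 0.39) and -0.40 in M2 (-0.73 to -0.17), against bounds of -0.58 and -0.45 set as a fixed share of the class II median. The M0 interval lies above that bound, but 9 of 14 markers (11 of 14 in M2) were at least 4-fold above the floor, and a condition on this, set after the values were seen, left the test undecided. Over the 11 of 14 markers well above background on both arrays of a state, the medians were 0.12 in M0 and -0.41 in M2.

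For KO against WT the 6 arrays give 10 splits into 3 and 3, too few for a share under 0.05. At an adjusted p of 0.05 the real split called 0 genes and the highest of the others 0; with a real count of 0 all 10 of 10 splits are as large whatever the data, so this count decides nothing. At an unadjusted p under 0.05 the real split gave 2157 genes and the highest other 2473, so 2 of 10 were as large. Only 4 of the splits part the 2 arrays of every state, as the real one does, with 2157, 2473, 502 and 197 genes, so 2 of these 4 were as large. The others rest on the arrays of a single state, since the fit has a term for state. The split with 2473 sets WT M0, WT M1 and KO M2 against the rest and so keeps the 2 arrays of slide 1 together. For KO against WT 0 genes passed with the slide as a block and 0 without it, so that count says nothing about the slide.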
